A study of Mus musculus with 3 samples.

How the data were processed

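The series holds 3 single-colour Affymetrix arrays of mouse bone-marrow mesenchymal progenitors, biotin-labelled from 1 µg of total RNA, per the labels' protocols. The cells came from mice aged 8 weeks and were cultured for 7 days in 1% oxygen, transduced overnight with lentiviral shRNA vectors and collected 4 days after transduction. Each array was assigned to control, HIF-1α or HIF-2α shRNA from its title in the labels, with 1 array in each group. The labels name no second culture or animal for any group.

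The authors deposited 1 table of RMA values, and RMA is named in the submitters' processing notes; its version, its settings and the annotation behind it are not given in the sources used here. RMA as usually run subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set by median polish over all arrays together. The deposited values are linear intensities, not log2, as their range shows: from 0.64 to 1747 on the control array, 0.63 to 1747 on the HIF-1α array and 0.64 to 1698 on the HIF-2α array, with medians of 1.41, 1.37 and 1.37. The upper quartiles were 9.8, 13.0 and 13.9, so the control array was dimmer around its upper quartile, though not at its median. Many values were exactly equal between arrays, which median polish over few arrays can produce: among the 4663 probe sets of at least 64, 22.7% were equal on the control and HIF-1α arrays, 17.0% on the control and HIF-2α arrays and 23.1% on the HIF-1α and HIF-2α arrays. Where values are equal, a small difference may not have been recorded. Signal over background stands in for depth on an array: the highest of 23 nonspecific control probe sets was 3.47 on the control array, 2.29 on the HIF-1α array and 3.29 on the HIF-2α array. Pearson's r between arrays across probe sets of at least 64 was 0.960 for control and HIF-1α, 0.910 for control and HIF-2α, and 0.958 for HIF-1α and HIF-2α. Across all probe sets, most of them dim, r was 0.989, 0.984 and 0.996 in the same order. Equal values there made up 32.5%, 31.0% and 58.1%, so the HIF-1α and HIF-2α arrays were the most alike pair by both measures.

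The analysis took log2 of the deposited intensities with no further scaling. The platform table listed genes for 29449 probe sets, of which 28898 had 1 gene and 551 had several; another 15588 probe sets other than controls were not listed and stay unnamed. Of those with 1 gene, 28689 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, and that table was used for names alone. Control probe sets (104) and probe sets with no or several genes were left out of gene counts. Each of the 17097 genes was represented by its probe set with the highest mean over the 3 arrays, and 2738 genes were called measured because that probe set reached 64 (6 on the log2 scale) on at least 1 array. That minimum had been chosen before the data were examined for values expected on a log2 scale, and it is strict for this table. Among 649 genes with at least 2 measured probe sets, the pooled SD between probe sets of the log2 difference was 0.12 for HIF-1α against control, 0.21 for HIF-2α against control and 0.14 for HIF-2α against HIF-1α. This is a technical spread within an array pair and says nothing of the spread between cultures.

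With no replicates no test was run across arrays and no p-value is given. Genes were counted by a rule of size, a difference of at least 2-fold, in 3 comparisons: each shRNA array against control, and HIF-2α against HIF-1α. Where the dimmer of 2 values lay under 3.47, the fold is given as a lower bound against 3.47. For 23 gene lists fixed before the data were examined, the median difference of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 measured members was said to stand apart when its percentile was under 2.5 or over 97.5, as a description of these arrays. The lists covered HIF pathway components, hypoxia-induced genes, glycolysis, HIF-2 preferred genes, oxidative phosphorylation, cell cycle, p53 targets, interferon response, inflammatory cytokines, integrated stress and unfolded protein response, cholesterol synthesis, TGF-β and YAP targets, extracellular matrix, osteogenic, adipogenic and chondrogenic genes, niche factors, sex-linked transcripts, and markers of mesenchymal, haematopoietic, erythroid, endothelial and smooth muscle cells. Because the shRNA arrays share a control, the resemblance of their differences was set beside 1000 simulations of unchanged arrays that share a simulated control. The noise of each simulated array was drawn from the spread of the difference between the shRNA arrays, in bins of mean expression. Real differences between the hairpins therefore count as noise in it.

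Genes named in the text follow a rule fixed before the data were examined. It takes Hif1a and Epas1, the 6 highest and 6 lowest differences of each shRNA array against control, and the 4 highest and 4 lowest of HIF-2α against HIF-1α, among genes with an established symbol whose measured probe sets differ in the same direction. It adds 3 members of each list that stood apart from control and, for any other list, its most different member if that is past 2-fold. It gave 41 genes, of which 2 (H2-Ab1 and Xist) were read by probe sets shared between transcripts. Marker genes of other cell types and any gene said to be chosen after its values were seen stand outside the rule.

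The procedure was tested on simulated arrays of 2738 genes with a noise SD of 0.220 per array, taken from the difference between the shRNA arrays. Of 200 genes changed 2-fold, 49.5% passed the 2-fold rule, as a change at the threshold should, with 4 unchanged genes past it; of 200 genes changed 4-fold, 100.0% passed, with 5 unchanged genes past it. For lists of 16 genes, 8 of 100 unchanged lists stood apart and 50 of 50 lists shifted by 0.4 did. Smaller shifts were not simulated, and the simulated noise was continuous and independent between genes, without the equal values of the real arrays. The test therefore does not cover lists with small medians. Alternatives set before the data were examined were no minimum on brightness, a minimum of 7 on the log2 scale, the mean of all probe sets of a gene, 32 added before log2, cyclic loess scaling, thresholds of 1.5-fold and 3-fold, random lists not matched on expression and the mean of a list in place of its median. A minimum of 16 and raising values to the nonspecific level were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and cyclic loess used limma 3.58.1 in R 4.3.3. The files name no genome build, so no coordinates are given.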

Results

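Gene expression was measured on 3 oligonucleotide arrays of cultured mouse mesenchymal progenitors, the stromal cells of bone marrow that form fibroblast colonies. The cells, called PaS+ in the labels, were sorted by FACS from 8-week-old animals, grown in 1% oxygen and transduced overnight with lentivirus carrying a short hairpin RNA (shRNA). One array held cells given a control shRNA, 1 held cells given an shRNA against HIF-1α and 1 held cells given an shRNA against HIF-2α, the oxygen-regulated subunits of the hypoxia-inducible transcription factors. RNA was collected 4 days after transduction. With 1 array per shRNA there was no replicate, so no difference could be set against a spread between samples and none was tested. Each array reported 45141 probe sets, of which 4143 on the control array, 4364 on the HIF-1α array and 4421 on the HIF-2α array reached an RMA intensity of 64, the minimum used for calling a gene measured. This left 2738 measured genes, and the number of arrays limits the precision of every value given for them.

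The targeted genes came first, because they check the labels. Hif1a (Entrez gene 15251) stood at 352.1 on the control array and at 332.4 on each of the shRNA arrays, which is 94.4% of control with either hairpin. The probe set that measured it therefore gave no lower value with the hairpin against Hif1a than with the other one. Epas1, which encodes HIF-2α (Entrez gene 13819), was dim on all 3 arrays, at 5.09 on the control array, 9.44 with the HIF-1α hairpin and 3.21 with the HIF-2α hairpin, against a highest nonspecific probe set of 3.47. It was thus 1.85-fold higher than control with the first hairpin and at least 1.47-fold lower with the second, where it lay under the nonspecific level. Because Hif1a did not separate the hairpins, the arrays are called the HIF-1α-labelled and HIF-2α-labelled arrays in what follows, and each direction rests on those labels.

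The comparison of the HIF-1α-labelled array with control asks what differed in progenitors given the hairpin against HIF-1α under low oxygen. Genes of the antiviral interferon response were far brighter on the HIF-1α-labelled array. Ifit1, whose product binds foreign RNA and blocks its translation, read 93.8 against 1.04 on the control array and was at least 27.0-fold higher. Usp18, which trims ISG15 from proteins and dampens interferon receptor signalling, was at least 18.9-fold higher, and Ifit3, a partner of Ifit1, at least 17.8-fold. Rtp4, an interferon-induced receptor chaperone that was above the nonspecific level on every array, was 18.1-fold higher, at 167.8 against 9.27. Zbp1, a sensor of Z-form nucleic acid, was at least 9.97-fold higher and the oligoadenylate synthetase gene Oas1g at least 4.76-fold. A bound of this kind divides the brighter value by 3.47 where the dimmer value lay under that level.

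All 8 measured members of the interferon list were at least 2-fold higher on the HIF-1α-labelled array, with a median log2 difference of 3.69. With control values under the nonspecific level raised to it, that median was 3.49. In either case it lay at percentile 100 of 10000 random lists of the same size and brightness. These 8 genes read at most 21.4 on the control array and counted as measured only through an shRNA array, so the minimum of 64 itself favoured large differences among them, and 12 other members on the array stayed under it. Without any minimum 17 of the 20 members were past 2-fold, the exceptions being the antiviral GTPase genes Mx1 (−0.09) and Mx2 (0.31) and the oligoadenylate synthetase-like gene Oasl1 (0.71), and the median was 2.89. With 32 added before log2 the median of the 8 genes was 1.5, and Oas1g, at 0.54, was under 2-fold. Among 16 measured inflammatory cytokines and NF-κB targets, 14 were above 0 and 1, the T-cell-attracting chemokine gene Ccl5, was past 2-fold, at 404.9 against 146.5. The list's median was 0.14, at percentile 99.99. Icam1, a leukocyte adhesion molecule, was higher by 0.59 and the neutrophil chemokine gene Cxcl5 by 0.35 on the log2 scale.

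Hypoxia-induced genes lay slightly lower on the HIF-1α-labelled array. Of 23 measured members 18 were below 0, 2 above and 3 equal, and none differed 2-fold. Their median was −0.08, at percentile 0.00. The 3 members with the largest differences were Pfkfb3, a regulator of glycolytic flux, at −0.29, Ero1a, an oxidase of the endoplasmic reticulum, at −0.24, and Plod2, a collagen lysyl hydroxylase, at −0.19. Glycolysis genes showed a median of −0.09, also at percentile 0.00, with 9 of 12 below 0, 3 equal and none above. Aldoc (aldolase C) had a difference of −0.32, Hk2 (hexokinase) one of −0.30 and Pfkp (phosphofructokinase) one of −0.27.

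Across the 2738 genes 29 differed at least 2-fold between the HIF-1α-labelled and control arrays, 29 higher and 0 lower, against 519 higher and 84 lower without any minimum and 168 higher and 4 lower at a minimum of 16. The genes with the most negative differences therefore stayed under 2-fold on the probe sets that represent them. They were H2-Ab1, an MHC class II chain read by a probe set shared between transcripts, at −0.74, Thbs4, a thrombospondin of the matrix, at −0.60, Tlcd3a at −0.58, Timp3, an inhibitor of matrix metalloproteinases, at −0.55 (its 3 probe sets ranged from −1.11 to −0.55), Glipr1 at −0.55, and Cxcl12, the chemokine that holds blood stem cells in the marrow, at −0.49. Of the 29 genes, 8 had a control value under the nonspecific level. Averaging all probe sets of a gene took the glycolysis median to −0.05, and taking the mean of the inflammatory list in place of its median gave 0.24, and neither list then stood apart from random lists.

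The comparison of the HIF-2α-labelled array with control asks the same of the hairpin against HIF-2α. Interferon-induced genes were again those with the largest differences. Ifit1 reached 186.3 and was at least 53.7-fold higher than control, Usp18 at least 42.4-fold, Ifit3 at least 35.7-fold and Zbp1 at least 21.5-fold. Oas1g was at least 20.7-fold higher and Rsad2, which encodes the antiviral protein viperin, at least 18.4-fold. All 8 measured interferon genes were past 2-fold, with a median of 5.22, or 4.48 with control values raised to the nonspecific level, at percentile 100 both ways. Without any minimum 18 of the 20 members were past 2-fold, all but Mx1 and Mx2, and the median was 4.08. Mx1 and Mx2 were near or under the nonspecific level on this array too. With 32 added before log2 the median of the 8 genes was 2.19.

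The gene with the most negative difference on the HIF-2α-labelled array under the naming rule was Thbs4, which was 5.26-fold lower, at 12.7 against 66.6. The complement inhibitor gene Serping1 was 4.83-fold lower, the haemoglobin-binding acute-phase gene Hp (haptoglobin) 4.47-fold and the complement component gene C4b 4.25-fold. Cxcl12 was 3.46-fold lower, at 72.3 against 250.0, and Cbr2, a carbonyl reductase, 3.16-fold. With 32 added before log2 the log2 differences were −1.14 for Thbs4, −1.08 for C4b and −0.61 for Cbr2, the last under 2-fold, and the mean of the Cxcl12 probe sets gave −1.03.

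Extracellular matrix genes were lower as a group. All 16 measured members were below 0 on the HIF-2α-labelled array, 1 of them past 2-fold, and the list median of −0.42 lay at percentile 0.00. Col1a1, a chain of the main bone collagen, was 2.71-fold lower, at 48.1 against 130.4. Lum, a proteoglycan that organises collagen fibrils, had a difference of −0.98 and Col6a1, a chain of microfibrillar collagen, one of −0.73. The list median was −0.44 after cyclic loess scaling, −0.20 with a minimum of 7 on the log2 scale and −0.25 with the mean of each gene's probe sets. The 12 probe sets for the bacterial and phage hybridisation controls were dimmer on the same array, with a median of −1.02 and a range of −1.39 to −0.50, against a median of 0.08 on the HIF-1α-labelled array.

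**Figure D1:**
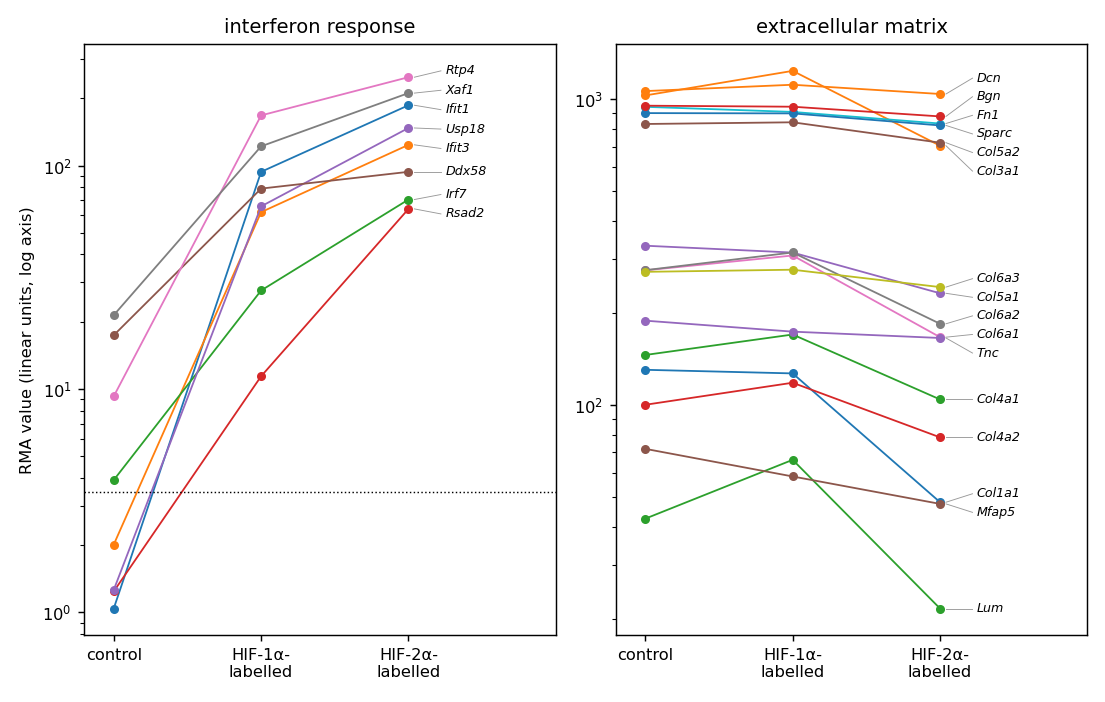
RMA intensities on a log axis for the measured members of the interferon list (left) and the extracellular matrix list (right), with 1 line per gene across the control, HIF-1α-labelled and HIF-2α-labelled arrays. The dotted line marks the highest nonspecific probe set, 3.47. All 8 interferon genes were at least 2-fold higher on each shRNA array, and all 16 matrix genes were lower than control on the HIF-2α-labelled array.

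Lists with fewer than 5 measured members are given as values. The 4 chondrogenic genes had a median of −0.84, with Col2a1, the cartilage collagen, 3.07-fold lower. The 2 adipogenic genes had a median of −1.17, with Lpl, the lipoprotein lipase of fat cells, 2.79-fold lower. Smooth muscle genes had 2 measured members and a median of −0.43. The 3 measured cell cycle genes had a median of 0.50. In the sex-linked list Xist, on a shared probe set, was 2.08-fold higher (0.93 on the log2 scale after cyclic loess, under 2-fold) and the list median over 2 genes was 0.55. Transcripts of both sexes were present, since the Y-linked Eif2s3y read 63.9 on the control array and 66.0 on each shRNA array.

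The inflammatory list had a median of −0.12 on the HIF-2α-labelled array, at percentile 0.37, but its mean was 0.02. Of 16 members 9 were below 0, 6 above and 1 equal. The collagenase gene Mmp13 had a difference of −0.78, the stromelysin gene Mmp3 one of −0.36 and the neutrophil chemokine gene Cxcl1 one of −0.29, whereas Ccl5 was 3.50-fold higher. Hypoxia-induced genes had a median of −0.05, at percentile 1.62, with 17 of 23 below 0 and none past 2-fold. Their most negative members were Selenbp1, a selenium-binding protein, at −0.76, Pfkfb3 at −0.44 and Mxi1, a repressor of MYC activity, at −0.32, although the mean of the Mxi1 probe sets gave 0.11. Glycolysis genes had a median of −0.04, at percentile 10.76, and so did not stand apart.

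In all 69 genes differed at least 2-fold between the HIF-2α-labelled and control arrays, 46 higher and 23 lower. Cyclic loess scaling gave 67 genes, split into 34 higher and 33 lower, and a minimum of 7 on the log2 scale gave 12 higher and 14 lower, so the excess of higher genes depended on the scaling and the minimum. Of the 46 higher genes 8 belonged to the interferon list. Further interferon-induced genes among them, such as Oas1g, Zbp1 and Trim30a, lie outside the list, so 8 understates their share.

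Several lists did not stand apart from random lists on either shRNA array. Oxidative phosphorylation (26 measured genes) had medians of 0.01 on the HIF-1α-labelled array and 0.05 on the HIF-2α-labelled array, and p53 targets with CDK inhibitors (10 genes) had medians of 0.00 and 0.01. Genes of the integrated stress and unfolded protein response (14) had medians of 0.05 and −0.03. For TGF-β and YAP targets (10) the medians were 0.06 and −0.03, for niche factors that sustain blood stem cells (7) 0.05 and −0.05, and for mesenchymal progenitor markers (6) 0.01 and −0.01. On the HIF-1α-labelled array the matrix list had a median of 0.02. Among lists too short to place, HIF pathway components (3) had a median of −0.08 on each shRNA array, and HIF-2 preferred genes (3) had medians of 0.01 and 0.00. The medians on the HIF-1α-labelled array were 0.50 for adipogenic genes, 0.16 for chondrogenic genes, −0.03 for cell cycle genes, 0.04 for smooth muscle genes and 0.43 for sex-linked transcripts. Cholesterol synthesis (2) had medians of 0.30 and 0.40.

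**Figure D2:**
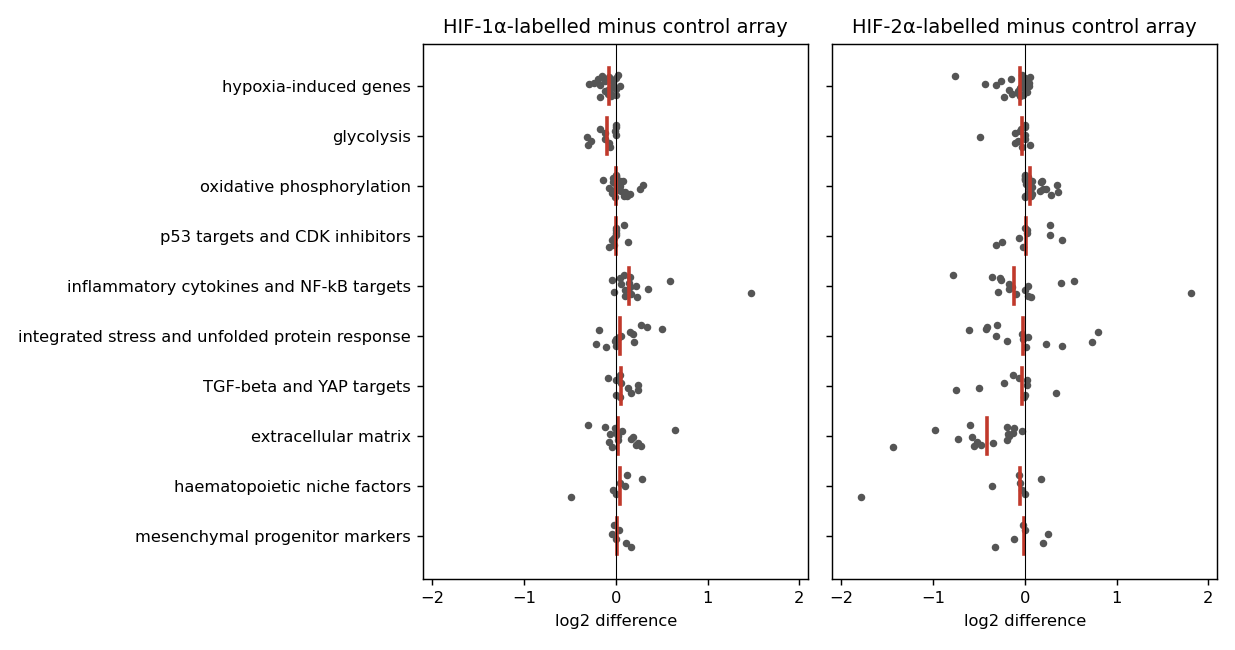
Log2 differences from control on the HIF-1α-labelled array (left) and the HIF-2α-labelled array (right) for the gene lists with at least 5 measured members other than the interferon list, with 1 point per gene and a red bar at each list median. The matrix median lies at 0.02 on the left and −0.42 on the right, and the hypoxia-induced medians at −0.08 and −0.05.

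Markers of blood and endothelial cells were near background, whereas some smooth muscle genes were not. None of the 17 haematopoietic and macrophage markers was measured. The control, HIF-1α-labelled and HIF-2α-labelled arrays gave medians of 1.35, 1.05 and 1.05 for these markers, and the macrophage gene Cd68 alone passed the nonspecific level, at 7.24 on the HIF-2α-labelled array. No erythroid marker passed that level on any array. Of 14 endothelial markers only Egfl7 did, at up to 5.45. Osteogenic genes had 0 measured members out of 10 on the array, and the brightest, Bmp2, reached 19.3. Of 11 smooth muscle and pericyte markers 5 passed the nonspecific level on each array, among them the smooth muscle actin gene Acta2, on a shared probe set, at 373.6 on the control, 428.7 on the HIF-1α-labelled and 232.9 on the HIF-2α-labelled array, and the tropomyosin gene Tpm2 at 316.0, 292.9 and 280.3. For the cultured cell type itself 11 of 12 mesenchymal progenitor markers passed the nonspecific level on each array.

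The direct comparison of the HIF-2α-labelled with the HIF-1α-labelled array leaves out the shared control array. It asks how the hairpins differed from each other. Interferon genes were higher with the HIF-2α hairpin: Rsad2 by 5.63-fold, Oas1g by 4.36-fold and Trim30a, an interferon-induced ubiquitin ligase, by 4.10-fold. The list median was 0.99, at percentile 100, with 8 of 8 members above 0 and 3 past 2-fold. The minimum of 64 favoured this direction, since Rsad2, Oas1g and Trim30a, and 3 of the 8 list members, reached it only on the HIF-2α-labelled array. Without any minimum the list median was 0.83, and the 5 members at 64 or more on the HIF-1α-labelled array were all brighter with the HIF-2α hairpin, by a median of 0.79. Ppbp, the precursor of a neutrophil-attracting chemokine, was 2.90-fold higher. In the other direction Cbr2 was 7.05-fold lower on the HIF-2α-labelled array, Hp 5.59-fold, Lpl 4.21-fold and Serping1 3.73-fold.

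Matrix genes were lower with the HIF-2α hairpin in this comparison too, with a median of −0.37 at percentile 0.00, 16 of 16 members below 0 and 2 past 2-fold, and a median of −0.19 without any minimum. The inflammatory list had a median of −0.22 at percentile 0.00, with 14 of 16 members below 0. Genes of the integrated stress and unfolded protein response had a median of −0.11 at percentile 0.90, TGF-β and YAP targets one of −0.12 at percentile 0.98, and niche factors one of −0.12 at percentile 2.20. The stress-response, TGF-β and YAP, and niche lists each failed to stand apart under some of the alternatives. Hypoxia-induced and glycolysis genes each had a median of 0.00. In total 46 genes differed at least 2-fold, 14 higher and 32 lower on the HIF-2α-labelled array, or 8 higher and 34 lower after cyclic loess. The balance turned with the minimum on brightness, to 137 higher and 81 lower without any and to 66 higher and 57 lower at a minimum of 16, and without any minimum the stress-response median turned to 0.12.

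**Figure D3:**
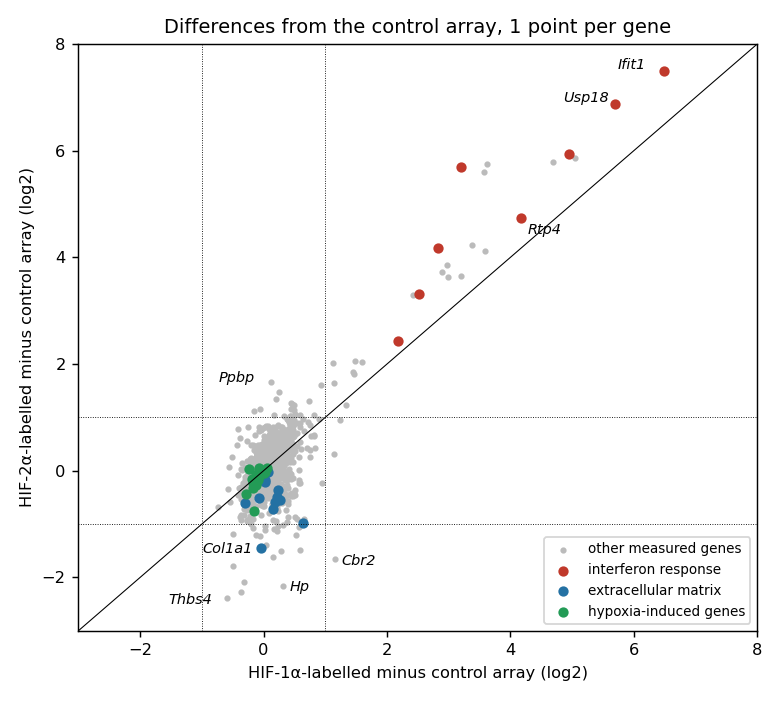
Log2 difference from the control array for each of the 2738 measured genes, on the HIF-1α-labelled array (horizontal axis) and the HIF-2α-labelled array (vertical axis), with interferon, matrix and hypoxia-induced genes coloured, dotted lines at 2-fold and a solid line of equal difference. Values under the nonspecific level enter as deposited. The 8 interferon genes lie at the upper right, and Cbr2 lies at 1.16 and −1.66.

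The differences from control on the HIF-1α-labelled and HIF-2α-labelled arrays were also compared with each other. Of the 29 genes at least 2-fold higher on the HIF-1α-labelled array, 26 were also at least 2-fold higher on the HIF-2α-labelled array. The other 3, named here after their values were seen, were Cbr2, the complement factor gene Cfb and the guanylate-binding protein gene Gbp2. On the HIF-2α-labelled array they differed from control by −1.66, 0.30 and 0.95, so Gbp2 was only just under 2-fold. Of the 26 shared genes all but Ccl5 and Lgals3bp read under 64 on the control array, so the minimum favoured such sharing. Among the 29 genes 25 were brighter with the HIF-2α hairpin than with the HIF-1α hairpin. The median difference was 0.79, but 13 of the 29 reached the minimum of 64 only on the HIF-2α-labelled array. Of the 16 that reached it on the HIF-1α-labelled array 12 were brighter with the HIF-2α hairpin, by a median of 0.48. Across genes, which are not independent replicates, Pearson's r between the differences was 0.81 and Spearman's rho 0.42. Unchanged arrays that share a simulated control gave 0.50 and 0.47, and an r near 0.50 follows from the shared control alone. Their noise was drawn from the difference between the shRNA arrays, so real differences between hairpins count as noise there. The covariance was 0.152 against a simulated 0.048, an excess of 0.104. Simulated arrays shared 4.3 higher genes on average and independent lists would share 0.49. Without the 8 genes of the interferon list r was 0.72 and rho 0.41. Neither rho was above the simulated 0.47, so ranks across all genes showed no resemblance beyond that of the simulation. Without the list 18 higher genes were shared, many of them known interferon-induced genes such as Oas1g, Zbp1 and Trim30a. Leaving out the list therefore does not take out the whole interferon response. The single control array could not be split, so part or all of the excess may come from it.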

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

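All tests of explanations in this part were chosen after the results were seen.

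Interferon-induced genes were brighter on both shRNA arrays, with all 8 measured members past 2-fold on each, and 17 and 18 of the 20 members on the array without any minimum. Blood cells carried into the transduced cultures would bring their own abundant transcripts, but at most 1 of 17 leukocyte markers passed the nonspecific level on an shRNA array (Cd68, at 7.24), none did on the control array, and the cells had been sorted before culture. A control array that alone deviated would leave the shRNA arrays alike. The interferon list differed between them by a median of 0.99 in 8 of 8 genes, or 0.83 over all 20 members without any minimum. That difference does not involve the control array, so a deviating control cannot account for it. The shift shared by both shRNA arrays, with a median of 3.69 on the HIF-1α-labelled array, could still come wholly from the control array. Other values also leave room for a deviating control. Over all probe sets r was 0.996 between the shRNA arrays, against 0.989 and 0.984 with control, though over those of at least 64 they were not the closest pair. Without any minimum 218 genes differed at least 2-fold between the shRNA arrays, against 603 and 1023 from control. The control cells were also transduced with an shRNA vector, so a response common to all such vectors would be expected on the control array too. A response particular to the 2 targeting vectors or their sequences, such as sensing of double-stranded RNA, is a candidate explanation. It cannot be told apart from loss of either HIF subunit, because each target had 1 vector. Hif1a itself differed by only −0.08 on the HIF-1α-labelled array. A biological effect of HIF loss on interferon signalling stays open and untested.

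Matrix genes were dimmer on the HIF-2α-labelled array, with a list median of −0.42. The hybridisation controls were dimmer on the same array, with a median of −1.02. A brightness-dependent shift would have been removed by comparison with genes of like brightness and by cyclic loess. The matrix median after loess was −0.44, which argues against a shift of that kind alone. Neither step tests what dimmed the hybridisation controls. Those controls read 44.6 to 930.2 on the control array and were all dimmer here, while the median of all measured genes was 0.02. A lower share of mesenchymal cells would lower markers confined to them by a like amount. The 6 measured markers (Nt5e, Cd44, Itgav, Cd34, Cd9 and Cd81) had a median of −0.01 with an SD of 0.21. Without any minimum the median of all 12 was 0.10, with a range from −0.96 for Thy1 to 0.60 for Alcam. Nothing here shows that these markers are confined to mesenchymal cells, so a lower share is not excluded. Loss of HIF-2α, an effect of this 1 vector and a difference between cultures stay open. So does a difference in hybridisation that does not follow brightness, and none of these was tested.

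Hif1a signal was not lost on the HIF-1α-labelled array. It read 332.4 on each shRNA array, so an exchange of these arrays would not account for the absent loss. If they had been exchanged, Epas1 should be higher on the HIF-2α-labelled array, and its difference between them was −1.55 as deposited. At values of 9.44 and 3.21 Epas1 is too near the nonspecific level of 3.47 to decide whether the labels are correct. Of 871 genes whose highest value was of like brightness, 18 differed at least 2-fold from control on an shRNA array. This argues against a general loss of 2-fold changes at this brightness, although some of the 18 were dim on control, such as Ifit1 at 1.04. It cannot exclude that summarisation hid a change in the Hif1a probe set itself, which was exactly equal on the shRNA arrays. A weak or transient knockdown, loss of protein without loss of transcript, and a probe set that reads another transcript may each account for the absent loss, and none was tested.

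The inflammatory list had a median of 0.14 on the HIF-1α-labelled array and −0.12 on the HIF-2α-labelled array, opposite in sign. Its means were 0.24 and 0.02, both above 0. In the direct comparison of HIF-2α with HIF-1α its median was −0.22, at percentile 0.00 of random lists. No test across cultures was possible for this difference because there is 1 array per group. Cbr2 differed from control by 1.16 on the HIF-1α-labelled array and by −1.66 on the HIF-2α-labelled array, the single gene past 2-fold in opposite directions; with 32 added before log2 the values were 0.70 and −0.61, both under 2-fold, and this difference too was not tested. Among control probe sets outside the comparisons, a probe set for bacterial phe read 4.47 on the HIF-2α-labelled array, above the nonspecific level of 3.47. The control probe set for the 3′ end of the transferrin receptor gene Tfrc read 15.1 on the HIF-2α-labelled array, 4.75 on the HIF-1α-labelled array and 2.30 on the control array. Among 1063 bright probe sets with no or several genes named, 8 were at least 2-fold higher and 1 lower on the HIF-1α-labelled array. On the HIF-2α-labelled array 12 were higher and 12 lower.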

How the results depend on the processing

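The minimum of 16 and the raising of values to the nonspecific level were chosen after seeing the data; the other alternatives were not. No leave-one-out check was possible with 1 array per group. No paired analysis was possible because the labels give no replicate numbers. The interferon list stood apart, higher, in all 3 comparisons, and the matrix list stood apart, lower, in both that involve the HIF-2α-labelled array, under every alternative run, except that a minimum of 7 on the log2 scale and the mean of probe sets gave no value for the interferon list because fewer than 5 members were left. Their sizes moved: the interferon medians or means lay between 1.5 and 4.10 on the HIF-1α-labelled array, 2.19 and 5.22 on the HIF-2α-labelled array and 0.76 and 1.08 between the shRNA arrays, and those of the matrix list between −0.45 and −0.20 on the HIF-2α-labelled array and −0.53 and −0.19 between the shRNA arrays. The hypoxia-induced list stood apart, lower, against control on both shRNA arrays under every alternative, between −0.09 and −0.05 on the HIF-1α-labelled array and −0.12 and −0.04 on the HIF-2α-labelled array. Of 285 list values under alternatives, 257 kept their side of the percentile limits without turning direction, 10 lost and 6 gained their standing, and 12 turned direction. Of 212 values of named genes 141 moved by less than 0.16, the pooled SD between probe sets, 70 moved further and 1 turned direction, Mxi1 on the HIF-2α-labelled array at 0.11 with the mean of probe sets. Of 31 named differences past 2-fold, 3 were under it in at least 1 alternative (Cbr2 and Xist against control on the HIF-2α-labelled array, Oas1g on the HIF-1α-labelled array). No rescaling moved the median of all genes by over 0.1.

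Counts of genes past the threshold moved with the minimum, the threshold and the damping of dim values. For HIF-1α against control (29) they were 603 with no minimum, 10 with a minimum of 7 on the log2 scale, 16 with 32 added, 172 with a minimum of 16 and 56 at 1.5-fold. For HIF-2α against control (69) they were 1023, 26, 36, 380 and 210 in the same order, 45 with the mean of probe sets and 34 at 3-fold. For HIF-2α against HIF-1α (46) they were 218, 21, 18, 123 and 160 in the same order, and 14 at 3-fold. The other counts stayed within 1.5 times.

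The causes of the following changes were not tested. Taking the mean of all probe sets, adding 32 and cyclic loess gave Epas1 0.52, 0.16 and 0.69 in the HIF-1α comparison, and −0.33, −0.08 and −0.90 in the HIF-2α comparison. The resemblance of the shRNA arrays was r = 0.60 with 32 added. With no minimum, the glycolysis median of −0.04 on the HIF-2α-labelled array came to stand apart, the matrix median on the HIF-1α-labelled array turned to −0.01, the stress-response and mesenchymal marker medians on the HIF-2α-labelled array turned to 0.03 and 0.10, and in HIF-2α against HIF-1α the stress-response median turned to 0.12 and the niche factor median was 0.00. With a minimum of 16, the stress-response median turned to 0.06 in that comparison and to 0.02 on the HIF-2α-labelled array, the mesenchymal marker median turned to 0.20 on the HIF-2α-labelled array, and TGF-β and YAP targets came to stand apart at 0.13 on the HIF-1α-labelled array. With a minimum of 7 on the log2 scale, the stress-response list came to stand apart at −0.20 on the HIF-2α-labelled array and p53 targets turned to −0.02 there, while TGF-β and YAP targets at −0.06 and niche factors at −0.14 no longer did in HIF-2α against HIF-1α. The mean of probe sets gave −0.05 for glycolysis and 0.13 for matrix genes on the HIF-1α-labelled array, −0.19 for the stress response on the HIF-2α-labelled array and −0.11 for TGF-β and YAP targets in HIF-2α against HIF-1α. Taking a list's mean gave 0.24 and 0.02 for the inflammatory list on the HIF-1α-labelled and HIF-2α-labelled arrays, −0.30 for niche factors on the HIF-2α-labelled array and −0.09 for the stress response in HIF-2α against HIF-1α. On the HIF-2α-labelled array cyclic loess turned the medians of glycolysis to 0.01, of p53 targets to −0.02 and of mesenchymal markers to 0.04. In HIF-2α against HIF-1α the stress response was −0.02 after cyclic loess, and niche factors were −0.09 with 32 added and −0.12 against unmatched random lists, none standing apart.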

Other observations

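The values in this part use a minimum of 16 in place of 64, chosen after seeing the data, and the genes were named after their values were seen. Proliferation genes, mostly too dim for the stricter minimum, were higher on the HIF-2α-labelled array. All 17 cell cycle genes measured at this level were above 0 there and 11 were past 2-fold, with a median of 1.37 at percentile 100, against a median of 0.28 for random lists of like brightness. The minimum itself favoured this: 7 of the 17 genes, all past 2-fold and including Top2a and Ccna2, reached 16 only on the HIF-2α-labelled array. The 7 genes at 16 or more on the control array were also all above 0, but only Mcm6 was past 2-fold and their median was 0.50. On the HIF-1α-labelled array the median of all 17 genes was 0.09, at percentile 14.04, and that of these 7 was 0.02. Between the shRNA arrays the median of all 17 was 0.98, at percentile 100, and that of the 7 was 0.57. Ccna2, the cyclin of S phase and early mitosis, read 6.21 on the control array, 15.0 on the HIF-1α-labelled array and 36.4 on the HIF-2α-labelled array. Top2a, the topoisomerase of dividing cells, read 13.9, 15.9 and 40.9, and Mcm6, a subunit of the replicative helicase, 21.4, 24.8 and 55.3. The median of all genes at this minimum was itself shifted, by 0.07 on the HIF-1α-labelled array and 0.10 on the HIF-2α-labelled array.

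Adipogenic genes differed in sign between the shRNA arrays. All 6 measured members were lower than control on the HIF-2α-labelled array, with a median of −0.75 at percentile 0.00, and 5 of 6 were higher on the HIF-1α-labelled array, with a median of 0.42 at percentile 97.92. Fabp4, the fatty-acid carrier of fat cells, read 298.1 on the control array, 394.0 on the HIF-1α-labelled array and 163.9 on the HIF-2α-labelled array, and the lipid-droplet gene Plin4 read 25.8, 35.1 and 12.4. The 6 chondrogenic genes had a median of −0.49 on the HIF-2α-labelled array, at percentile 0.00, with 5 below 0 and 1 equal, and Comp, a cartilage matrix protein, read 218.4, 324.5 and 105.1. All 9 cholesterol synthesis genes were above 0 on the HIF-1α-labelled array, with a median of 0.29 at percentile 98.15, among them the sterol demethylase gene Cyp51, at 38.8 against 28.1. On the HIF-2α-labelled array the cholesterol median was 0.12, at percentile 57.19.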
